A study of Macaca mulatta with 2 samples.

How the data were processed

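Single-cell RNA was measured in 2 samples of trabecular meshwork from 10-year-old rhesus macaques, which form 1 group with 2 replicates, here called sample 1 and sample 2. Per the labels' protocols, the tissue was dissected in oxygenated medium and digested with papain, about 10000 cells were loaded at 1000 cells per microlitre, and 3' version 3 droplet libraries were sequenced on a HiSeq 2500. Per the submitters' processing notes, the reads were processed with Cell Ranger 3.1.0. The genome build and the annotation are not given in the sources used here, so genes are named by the symbols and identifiers of the table and no coordinates are given. The table deposited by the authors holds raw UMI counts per gene and cell, without normalization, for 5158 cells and 32386 genes, of which 14653 have 0 counts. The filter that selected these cells is not given in the sources used here. The columns carry library names that differ from the sample titles, and the 2 sets were matched to the samples by the side of the eye and the tissue in both names; 0 columns were left over. Whether the samples come from 2 animals or from the 2 eyes of 1 animal is not settled by the labels. Every p-value below measures how far class differences vary between these 2 libraries, after the difference shared by all classes is removed. That spread is pooled over the classes and is not a spread between animals. Of 10557 identifiers without a symbol in the table, 1015 matched a symbol in the reference and 891 took it, where no other gene of the table had that symbol. The series was made to compare the cells of the outflow tissue between species; the other species were not analysed here.

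The minimum of 500 genes per cell removed 0 cells, since the shallowest cell had 601 genes. Doublets were predicted in each sample with Scrublet in scanpy 1.11.5 (expected rate 0.8% per 1000 cells, seed 0), and 44 cells (0.853%) were left out. Counts were scaled to 10000 per cell and log transformed, 2000 variable genes were chosen over both samples, scaled within each sample and limited to 10 SD, and 30 principal components were taken. A graph of 20 shared neighbours was clustered by the Leiden method at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, 10 iterations; Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0). No gene of the lists below was used to build the clusters, so the lists did not define the classes they were compared between; 15518 genes were open to the clustering.

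Clusters were named by 113 marker genes, of which 101 are in the table. A class needed 3 detected markers, each at 20 CPM (its counts scaled to the total of the cluster) or more and at least 1 log2 unit above the median of the other clusters, and the class with the highest mean z-score was taken. A meshwork cluster was named juxtacanalicular tissue (JCT) with 4 detected JCT markers and beam otherwise. One cluster of 120 cells held markers of both JCT and corneal endothelium and was split at resolution 0.5 into 2 parts. The markers were fixed in advance, but the naming rule was changed several times and several resolutions of the split were tried after the markers of the clusters had been seen and before any listed gene was tested. The chosen split was kept partly because resolution 1 left JCT-like cells of sample 1 under the 20 cells that a test required. Names are given as "like", since no protein or position in the tissue was measured. Of the beam-like clusters, 3 had no beam marker among their 10 leading genes. The genes ACTA2 and MYH11, markers of pericytes here, also led ciliary muscle-like clusters, and the JCT marker RSPO2 and the corneal endothelium marker COL8A2 were high in meshwork clusters in general.

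Raw counts were summed per sample and class for the 11 classes with at least 20 cells in each sample and fitted together in edgeR 4.0.16 (R 4.3.3; TMM scaling, filterByExpr, quasi-likelihood F test, two-sided) with terms for class and for sample as a block, leaving 10 residual degrees of freedom. The Benjamini-Hochberg adjustment ran over the 6796 genes tested in each comparison. A gene was called where the adjusted p was under 0.05, the log2 fold was at least 1 in size and both samples had the same sign. Each of the 11 classes was compared with the equal-weight mean of the other 10, and 4 pairs were compared: beam-like against JCT-like, Schlemm canal or lymphatic endothelium-like against blood vascular endothelium-like, ciliary muscle-like against pericyte or vascular smooth muscle-like, and the mean of beam-like and JCT-like against stromal fibroblast-like. The standard error (SE) of a fold is its size over the square root of F. Sums of one sample are not independent of each other, and 2 libraries carry all the replication. Levels are plain CPM of a class sum. In the pairs and between the samples, a fold against 0 counts is given as at least the ratio to 3 counts over the summed class. With 1 to 3 counts the ratio of CPM is given with its exact 95% counting interval. These ratios use library totals without TMM factors, unlike the fitted folds. A fold of a class against the mean of the others is the fitted one, also where some of those classes have 0 counts.

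Only listed genes are results: 212 genes in lists for early-onset glaucoma, open-angle glaucoma or pressure loci, exfoliation loci, angle closure loci, optic neuropathy, glaucoma drug targets, structural matrix, matrix turnover with TGF-beta and BMP, mechanosensing and water channels, contraction, glucocorticoid response, angiopoietin and VEGF, Wnt, and complement and cytokines. Of these, 194 are in the table, 188 have a count and 137 were tested. A quality list of 10 dissociation stress genes, 7 of them in the table, was summed per class. The named-genes rule took the class with the highest mean CPM for every measured gene of the early-onset, exfoliation and drug target lists; up to 12 called listed genes each way in each pair, by fold; and the 5 genes each way with the largest ratio between the samples, with at least 50 counts in 1 of them, in the 3 classes with the most cells in the smaller sample. Other genes named beside a list were chosen after their values were seen, and leading genes of clusters are description only. Lists, markers, tests, this rule and most alternatives were chosen before the data were examined. Between the samples the rule names classes, but beam-like and ciliary muscle-like cells are reported mainly by 1 cluster each. That limit was set after all clusters had been seen.

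Depth was 12155030 UMIs in sample 1 and 21911767 in sample 2. Shares of cells carry exact binomial 95% intervals and single counts exact Poisson intervals, both of which cover counting error only. The test was tried on simulated counts in which 100 genes were changed by 4-fold or 8-fold: 78% and 80% were called for beam-like against JCT-like, 70% and 81% for the endothelia, 53% and 62% for ciliary muscle against pericyte and 81% and 85% for meshwork against fibroblast, with 8, 10, 8 and 1 calls among the unchanged genes. The sums were drawn independently, at the spread fitted to these data and with the same class profile in both samples. These are best-case values, since real sums of one sample are not independent. The alternatives fixed in advance were the relative log expression size factors, no low-count filter, a DESeq2 1.42.0 Wald test, no sample block, a pooled reference, clustering with the listed genes, at resolution 0.5 or 2, with doublets kept or scaled over both samples together, a minimum of 200 or 1000 genes, thinning to 1000 UMIs, and each replicate left out. Added after seeing the data were library totals without scaling factors, a finer split of the mixed cluster, 2 reduced sets of beam-like clusters, and fits without 2 unnamed identifiers, alone or with the mitochondrial genes. Corneal endothelium-like cells, with 3 and 18 cells, were too few to test, and no correction for free RNA was made. Results for a few genes are not reported here.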

Results

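The 2 samples of rhesus trabecular meshwork gave 1593 and 3565 cells, with medians of 5755 and 4916 UMIs and 1774 and 1542 genes per cell. After predicted doublets were left out, 5114 cells (1582 and 3532) fell into 22 clusters and 12 cell classes. Mitochondrial genes held 20.4% and 21.4% of all UMIs, and 2 identifiers without a name held a further 17.9% and 18.0%. The median mitochondrial share per cell was 33.7% in ciliary muscle-like cells, which also had the most UMIs per tested class (median 12582), against 8.52% in beam-like cells. Schwann-like and T or NK-like cells were the shallowest per cell, with medians of 1692 and 1874 UMIs. Levels and tests use class sums, and the smallest tested sums were those of pericyte-like (58445 UMIs) and melanocyte-like cells (83212 UMIs) in sample 1. Low levels of a gene were hardest to detect there.

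The first question was which cells the dissected outflow tissue held. Beam-like meshwork cells, led by CP, BMP3, MGARP and CYP1B1, made up 31.0% of cells in sample 1 (95% interval 28.8 to 33.4, 491 cells) and 28.7% in sample 2 (27.2 to 30.2, 1012 cells). Ciliary muscle-like cells, led by ATP2A1, CHRM3, MYH11 and DES, made up 21.0% (19.1 to 23.1) and 25.4% (24.0 to 26.9), and macrophage-like cells 16.4% (14.6 to 18.4) and 19.3% (18.0 to 20.6). JCT-like cells, led by CYTL1, CCK, AQP5, ANGPTL7 and CHI3L1, were rarer, at 3.29% (2.46 to 4.29) and 1.33% (0.979 to 1.77). Leading genes were taken over the cells of both samples together. The listed gene AQP5 did not pass the low-count filter of the tests. Schlemm canal or lymphatic endothelium-like cells, led by the lymphatic genes CCL21 and MMRN1, were 5.94% (4.83 to 7.22, 94 cells) of sample 1 and 0.991% (0.691 to 1.38, 35 cells) of sample 2. Blood vascular endothelium-like cells, led by RNASE1, TM4SF1 and VWF, were 1.64% (1.08 to 2.40) and 2.10% (1.65 to 2.62).

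Schwann-like cells formed 7.40% (6.16 to 8.80) and 6.91% (6.09 to 7.80), in a cluster led by CDH19 and SCN7A and a smaller one of 38 cells led by myelin genes, MBP and PRX among them. Stromal fibroblast-like cells, led by PI16, DCN and SFRP4, formed 5.25% (4.20 to 6.46) and 6.37% (5.59 to 7.23), and T or NK-like cells 5.18% (4.14 to 6.39) and 4.13% (3.50 to 4.84). Pericyte or vascular smooth muscle-like cells formed 1.33% (0.824 to 2.02) and 2.66% (2.16 to 3.25), and melanocyte-like cells 1.26% (0.774 to 1.95) and 1.67% (1.27 to 2.15). Corneal endothelium-like cells were 3 and 18. No cluster was named as corneal epithelium, ciliary or iris epithelium, B cell or mast cell. The melanocyte-like cluster had TTR, a marker of ciliary or iris epithelium here, among its leading genes beside PMEL and TYR. Whether cells of that epithelium are among them was not tested. With 1 group of 2 samples the shares were not tested. The JCT-like share depended on how the cluster mixed with corneal endothelium-like cells was split, and fell to 1.14% and 0.595% with a finer split. That split gave 37 and 44 corneal endothelium-like cells in place of 3 and 18. All JCT-like results below hold for the class as split here.

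**Figure D1:**
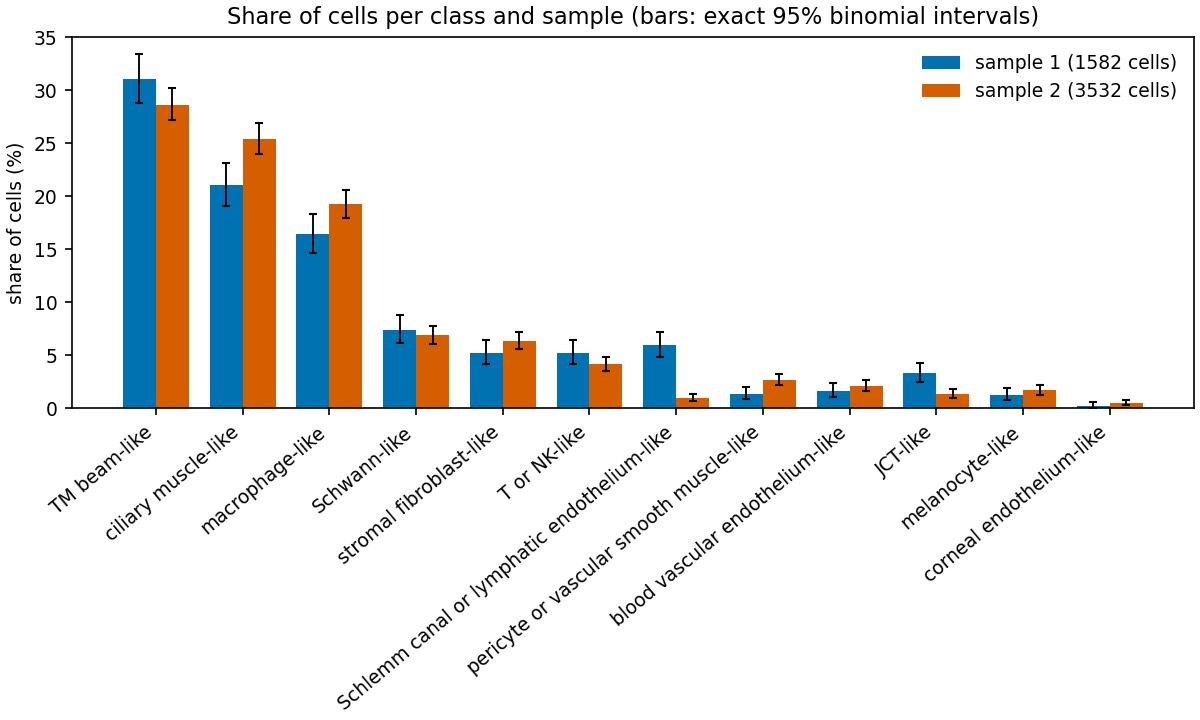
Share of cells in each class as a percentage of all cells of a sample (2 samples, bars with exact binomial 95% intervals). Beam-like, ciliary muscle-like and macrophage-like cells lead in both samples, and the Schlemm canal or lymphatic endothelium-like share is 5.94% in sample 1 and 0.991% in sample 2.

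The next question was where genes tied to glaucoma were expressed. MYOC, a secreted protein whose mutations cause early-onset glaucoma, had its highest level in JCT-like cells (29248 ± 3029 CPM, mean ± SD, n = 2), followed by beam-like cells (18135 ± 2935 CPM). Its level in T or NK-like and macrophage-like cells, which should lack it, was 189 and 138 CPM. Whether these counts come from free RNA, doublets or misplaced cells was not tested. CYP1B1, a cytochrome P450 of congenital glaucoma, was highest in beam-like cells (758 ± 133 CPM, against 168 in fibroblast-like cells, the next class). The TIE2 receptor ligand ANGPT1 (301 ± 166 CPM, against 173 in pericyte-like cells) and the matrix protein SVEP1 (215 ± 129 CPM) were highest in JCT-like cells. EFEMP1, a fibulin (114 ± 7.2 CPM), and COL4A1, a basement membrane collagen (1516 ± 286 CPM), were highest in Schlemm canal-like cells, and the transcription factor FOXC1 in fibroblast-like cells (355 ± 57 CPM). Each of these genes passed the edgeR test in its highest class against the other classes, with log2 folds from 3.07 (FOXC1) to 5.84 (SVEP1). The class was picked by the same counts and set against the mean of the others. Passing thus does not show that it exceeds the next class. ANGPT1 and FOXC1 were also called higher in pericyte-like cells (log2 folds 3.65 and 2.70).

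Drug targets also differed by class. Each one named here was called in its highest class, which was picked by the same counts. CHRM3, the muscarinic receptor through which pilocarpine contracts the ciliary muscle, reached 1502 ± 42 CPM in ciliary muscle-like cells against 98.9 in the next class, a log2 fold of 7.93 ± 0.20 (SE) over the other classes. The prostaglandin F receptor PTGFR, the target of latanoprost, was highest in JCT-like cells (167 ± 118 CPM, against 65.2 in fibroblast-like cells), the E2 receptor PTGER2 in beam-like cells (115 ± 13 CPM) and PTGER4 in macrophage-like cells (198 ± 27 CPM). The nitric oxide synthase NOS3 was highest in blood endothelium-like cells (101 ± 8.4 CPM), and the nitric oxide receptor subunits GUCY1A1 (165 ± 57 CPM) and GUCY1B1 (371 ± 16 CPM) in pericyte-like cells. The carbonic anhydrase CA12 had its highest mean of the 11 tested classes in JCT-like cells, but with 1 count in sample 1 and 61 in sample 2 it rests on sample 2. It is also a leading gene of the corneal endothelium-like cells, which were not ranked and were split from the same mixed cluster. Among exfoliation loci, CACNA1A was highest in JCT-like cells (60.2 ± 17.4 CPM), POMP in macrophage-like cells (412 ± 14 CPM) and RBMS3 in Schwann-like cells (270 ± 120 CPM). Their next classes were close, within the larger of the 2 SDs, at 49.3 CPM in beam-like cells for CACNA1A and at 391 and 177 CPM in blood endothelium-like cells for POMP and RBMS3. AGPAT1, with 64.1 CPM in Schwann-like cells but highest in ciliary muscle-like cells after TMM scaling, was not called.

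Of the early-onset, exfoliation and drug target genes with a count (14, 6 and 19), 8, 4 and 10 had enough counts for a test. TEK, the angiopoietin receptor, was at 14.9 ± 2.4 CPM in Schlemm canal-like and 13.2 CPM in blood endothelium-like cells, and CPAMD8 had its highest mean in blood endothelium-like cells (35.3 CPM) and LMX1B in beam-like cells (8.37 CPM). LTBP2, ADRA2C and ADORA1 had their highest means in JCT-like cells (23.4, 32.1 and 5.29 CPM), though LTBP2 had 13 counts there in sample 1 and 1 in sample 2, and ADORA1 had 2 and 1. The highest class of LTBP2 and TEK was not the same in both samples. Another 10 lay between 1.51 and 24.3 CPM in their highest class, which was JCT-like for LOXL1 and PAX6, Schlemm canal-like for PXDN and PTGER3, pericyte-like for TMEM136 and ADRA2A, melanocyte-like for PTGER1 and CA2, blood endothelium-like for ADRB1 (ciliary muscle-like after TMM scaling) and fibroblast-like for SLC6A2. These 10 rest on at most 10 counts in a sample, ADRB1 and ADRA2A on 1 in all, and for 7 of them (not PTGER1, CA2 and SLC6A2) the highest class was not the same in both samples. SEMA6A and CA4 had 0 counts. At these depths a lack of signal is not a lack of expression.

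**Figure D2:**
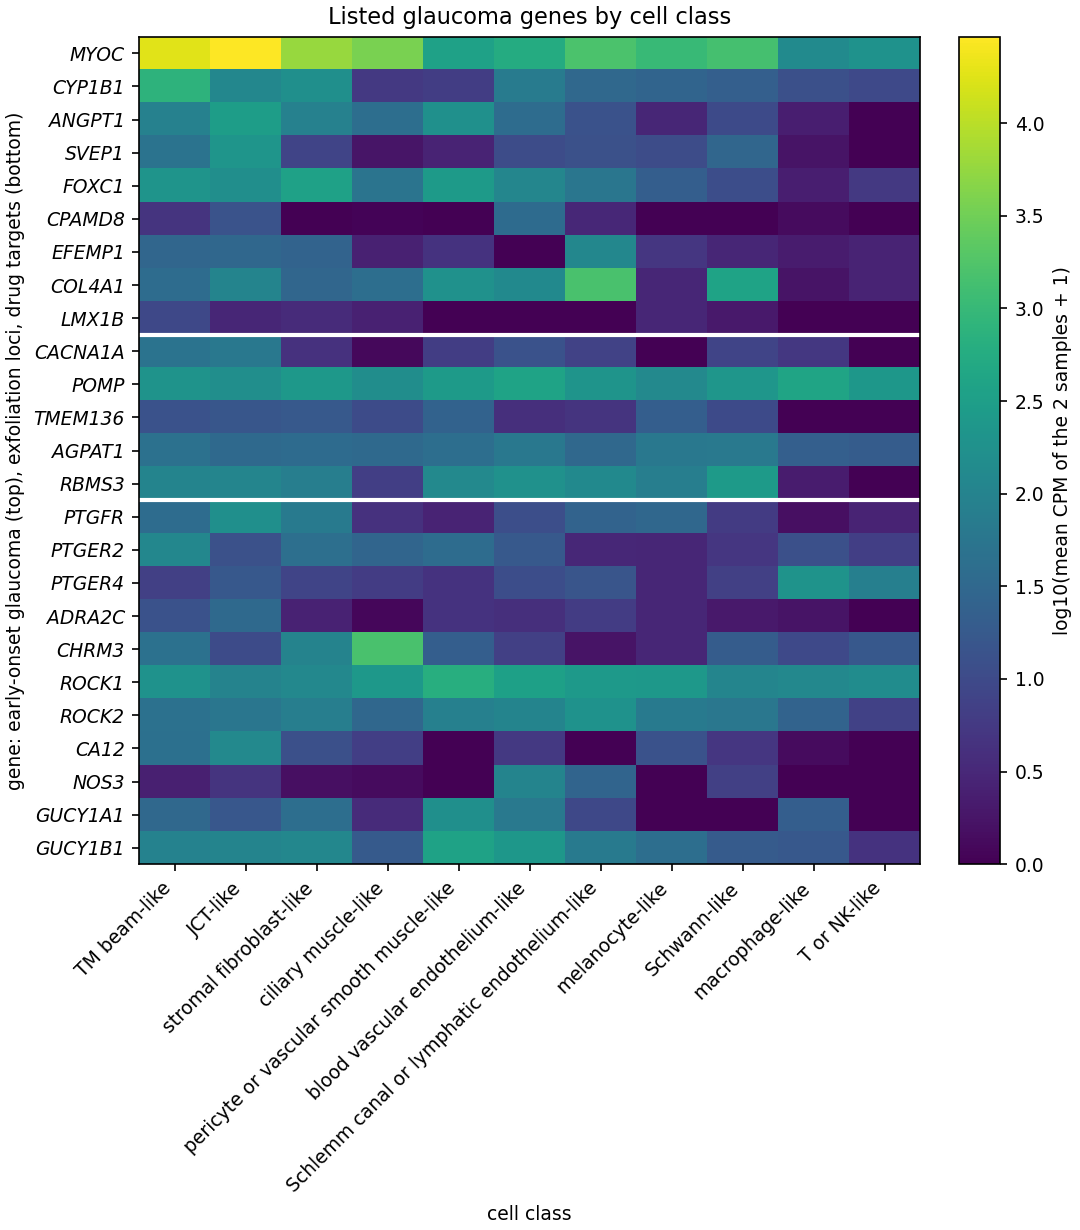
Heatmap of log10(mean CPM of the 2 samples + 1) for genes of the early-onset, exfoliation and drug target lists by cell class. MYOC reaches 29248 CPM in JCT-like cells and CHRM3 1502 CPM in ciliary muscle-like cells.

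Each class was then compared with the mean of the other classes, to ask which listed genes set it apart. The counts per list, here and in the pairs below, were not set against the share of calls over all 6796 tested genes. They therefore do not show that a list is enriched in a class. Values in parentheses are log2 folds ± SE. Where a gene had 0 counts in some of the other classes, the size of its fold is set by the fit and is not a measured ratio. Among the genes below, GREM1, SFRP2, POSTN, PTPRB, CFD and C3 are examples, each with 0 counts in melanocyte-like cells in both samples. In JCT-like cells 67 of 137 listed genes were higher, 1 lower (the drug target ROCK1, -1.02) and 69 did not pass (adjusted over the list alone, 70 and 3). All 8 tested early-onset genes, 20 of 22 structural matrix genes, 8 of 9 Wnt genes and 10 of 20 matrix turnover genes were higher (adjusted over the list alone, 8, 20, 8 and 10). Examples are GREM1, a BMP antagonist (8.79 ± 0.66), SFRP2, a secreted Wnt antagonist (7.53 ± 0.47), the chemokine CXCL14 (6.54 ± 0.29) and the fibulin FBLN1 (6.28 ± 0.28). In beam-like cells 73 were higher, 4 lower and 60 not passing (adjusted over the list alone, 74 and 4), with 7 of 8 early-onset, 15 of 22 structural matrix, 8 of 9 Wnt and 13 of 20 matrix turnover genes higher and 2 of the last list lower (adjusted over the list alone, 7, 15, 8, 13 and 2). WIF1, a Wnt inhibitor (5.02 ± 0.31), CYP1B1 (4.77 ± 0.19) and BMP4 (4.23 ± 0.26) were among them, and TGFBR2 (-2.94 ± 0.35) and TGFB1 (-1.86 ± 0.25) were lower. Of 10 contraction genes 6 were higher in beam-like cells (also adjusted over the list alone), and the calls of 3 of them turned with the reference. Against the pooled cells of the other classes, where ciliary muscle-like cells gave 15693470 UMIs, MYL9 was at -2.55, TPM1 at -1.65 and CAV3 at -2.22, and the counts became 44 higher and 31 lower for beam-like and 35 and 17 for JCT-like cells.

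Fibroblast-like cells had 66 listed genes higher, 7 lower and 64 not passing (adjusted over the list alone, 68 and 8), among them 14 of 22 structural matrix and 12 of 20 matrix turnover genes higher (15 and 12 adjusted over the list alone), with SFRP4 (8.77 ± 0.31), IL33 (6.90 ± 0.57) and VCAN (6.47 ± 0.44). Schlemm canal-like cells had 55 higher, 14 lower and 68 not passing (57 and 14 adjusted over the list alone), and without sample 1 the lower genes numbered 9. In them 7 of 12 angiopoietin and VEGF genes were higher and 2 lower, 11 of 21 open-angle or pressure loci higher and 3 lower, and 12 of 22 structural matrix genes higher and 0 lower (adjusted over the list alone, 7 and 2, 11 and 3, 14 and 0). The higher ones include POSTN (9.90 ± 0.37), PTPRB, a phosphatase that acts on TIE2 (8.42 ± 0.48), TIE1 (6.96 ± 0.30) and CAV1 (4.60 ± 0.23). Blood endothelium-like cells had 39 higher, 6 lower and 92 not passing (39 and 7 adjusted over the list alone), with 8 of 12 angiopoietin and VEGF genes higher and 1 lower (also adjusted over the list alone), among them VEGFC (8.02 ± 0.43), KDR (5.98 ± 0.36) and FLT1 (5.57 ± 0.24).

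Pericyte-like cells had 44 higher, 3 lower and 90 not passing (44 and 6 adjusted over the list alone), and 9 of 10 contraction genes were higher (also adjusted over the list alone). Among them were CNN1 (4.64 ± 0.30) and TAGLN (4.19 ± 0.23). MYLK (2.83) turned to -1.06 against pooled cells. Ciliary muscle-like cells had 40 higher, 22 lower and 75 not passing (40 and 22 adjusted over the list alone), with 8 of 10 contraction genes higher and 1 lower (8 and 1 adjusted over the list alone), among them CNN1 (6.22 ± 0.18), MYLK (6.02 ± 0.17) and MYL9 (5.43 ± 0.14). With library totals in place of TMM factors, the median of all genes in this class shifted by -0.99 and the counts became 26 higher and 37 lower (41.3% higher in place of 64.5%). Schwann-like cells had 30 higher, 9 lower and 98 not passing (32 and 9 adjusted over the list alone), led by GAS7 (5.55 ± 0.51) and WIF1 (5.18 ± 0.47), with 10 of 22 structural matrix genes higher (11 adjusted over the list alone). Melanocyte-like cells had 11 higher, 15 lower and 111 not passing (11 and 15 adjusted over the list alone), with CAV1 (4.24 ± 0.34) and OPTN, an optic neuropathy gene (2.77 ± 0.27), among the higher.

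In immune cells most called genes were lower. Macrophage-like cells had 17 listed genes higher, 45 lower and 75 not passing, and T or NK-like cells 7, 56 and 74 (adjusted over the list alone, 17 and 45, and 7 and 58). Structural matrix genes were lower for 14 of 22 (2 higher) and 12 of 22 (0 higher), and contraction genes for 8 of 10 and 7 of 10 (adjusted over the list alone, 14, 14, 8 and 7 lower). The higher genes in macrophage-like cells included the complement genes CFD (9.60 ± 0.35) and C3 (8.05 ± 0.31) and the chemokine CCL2 (6.17 ± 0.22), and in T or NK-like cells TGFB1 (4.92 ± 0.15). Of the mechanosensing list only YAP1, a mechanically regulated transcription cofactor, was tested, and it was higher in JCT-like (1.82), ciliary muscle-like (1.77), Schlemm canal-like (1.48) and beam-like cells (1.45) and lower in T or NK-like cells, also adjusted over the list alone, by which it was higher in fibroblast-like cells too; the call in ciliary muscle-like cells ended with library totals. Against the pooled reference 12 calls over the 11 classes turned direction, among them CHRM3 in beam-like (1.27 to -4.80) and fibroblast-like cells (2.47 to -3.21) and CCL2 in both endothelia. Library totals shifted the median of all genes by 0.38 in blood endothelium-like, 0.34 in Schlemm canal-like, 0.21 in melanocyte-like, 0.20 in Schwann-like, 0.17 in fibroblast-like, 0.14 in beam-like, 0.11 in pericyte-like, -0.15 in T or NK-like and -0.35 in macrophage-like cells, and relative log expression factors by -0.14 in ciliary muscle-like cells. Calls of a class against the others hold for a mean in which each class weighs the same.

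The first pair asked how the beam-like and JCT-like cells of the meshwork differ. The naming parted them narrowly. The JCT-like cluster detected 4 JCT markers, the number needed for that name, and also 5 beam markers. The beam-like clusters of 524, 338 and 166 cells each detected 3 JCT markers. JCT-like cells here numbered 52 and 47. The finer split of the mixed cluster named most of them corneal endothelium-like and left too few for a test. The differences below thus hold for the JCT-like class as split here. Beam-like cells carried more of the prostaglandin receptor PTGER2 (log2 fold 3.21 ± 0.55, edgeR adjusted p = 1.38e-04), CYP1B1 (2.48 ± 0.34, edgeR adjusted p = 6.69e-06) and the TGF-beta co-receptor TGFBR3 (2.36 ± 0.25). JCT-like cells carried more DKK2, which fell by 6.27 ± 0.41 on the log2 scale in beam-like cells (edgeR adjusted p = 6.23e-11), GREM1, which fell by 4.08 ± 0.48, and SFRP2, which fell by 3.44 ± 0.34. The 2 prostaglandin receptors thus went opposite ways, with PTGFR at -2.38 ± 0.34 (edgeR adjusted p = 9.84e-06). MYOC was abundant in both, with a log2 fold of -1.01 ± 0.63 that did not pass (edgeR adjusted p = 0.396).

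Of the 137 listed genes 12 were higher in beam-like cells, 26 lower and 99 did not pass (16 and 30 adjusted over the list alone). Structural matrix genes were 1 higher, 11 lower and 10 not passing (1 and 11 adjusted over the list alone). With library totals 1 was higher and 8 lower. POSTN, a matricellular protein, had 0 counts in beam-like cells and 17 in JCT-like cells, and was at least 82.3-fold lower. VCAN had 1 count in beam-like and 5 in JCT-like cells (ratio 72.6, interval 8.12 to 3434), and COL1A1 (-2.47 ± 0.30) and FBLN1 (-2.42 ± 0.34) were lower while the laminin LAMB1 was higher (1.85 ± 0.27). Matrix turnover genes were 2 higher, 4 lower and 14 not passing (2 and 5 adjusted over the list alone), with the protease ADAMTS1 (2.46 ± 0.41) and TGFBR3 higher, and GREM1 and TGFB1 (-2.83 ± 0.33) lower. Contraction genes were 3 higher, 0 lower and 7 not passing (5 and 0 adjusted over the list alone; 6 and 0 with library totals), namely TPM1 (1.45 ± 0.28), MYL9 (1.33 ± 0.29) and TAGLN (1.26 ± 0.39, edgeR adjusted p = 0.0379). Wnt genes were 0 higher, 3 lower and 6 not passing (0 and 3 adjusted over the list alone).

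Early-onset genes were 1 higher, 3 lower and 4 not passing (1 and 3 adjusted over the list alone), with SVEP1 (-2.30 ± 0.29), ANGPT1 (-1.91 ± 0.22) and COL4A1 (-1.61 ± 0.28) lower. Drug targets were 1 higher, 1 lower and 8 not passing (2 and 1 adjusted over the list alone, and with library totals), while angiopoietin and VEGF genes were 1, 1 and 10, with NRP2 higher (1.54 ± 0.25). There were 1, 2 and 6 complement and cytokine genes, with CXCL14 lower (-2.64 ± 0.27). The last 2 lists had the same counts adjusted over the list alone. Open-angle loci were 1, 1 and 19, with ME3 (2.18 ± 0.55) and THSD7A (-2.69 ± 0.84), and angle closure loci 1, 0 and 2, with FERMT2 (1.22 ± 0.36); these counts too held adjusted over the list alone. Exfoliation loci, glucocorticoid response genes, optic neuropathy genes and YAP1 were not called, and adjusted over the list alone 1 optic neuropathy gene was lower. ANGPTL4 (-3.30 ± 0.89) rests on sample 2, with folds of -0.30 in sample 1 and -3.64 in sample 2. Its call ended when JCT-like cells were clustered at resolution 2 (-0.30) or with the listed genes (-0.26). PTGER2 (4.49 in sample 1, 2.19 in sample 2) and FERMT2 (1.63, 0.68) were weaker in sample 2. The calls of TAGLN, FERMT2 and MYL9 ended without the sample block and that of THSD7A with library totals. Library totals shifted the median of all genes by 0.18 and moved the share of calls that were higher from 31.6% to 43.6%.

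**Figure D3:**
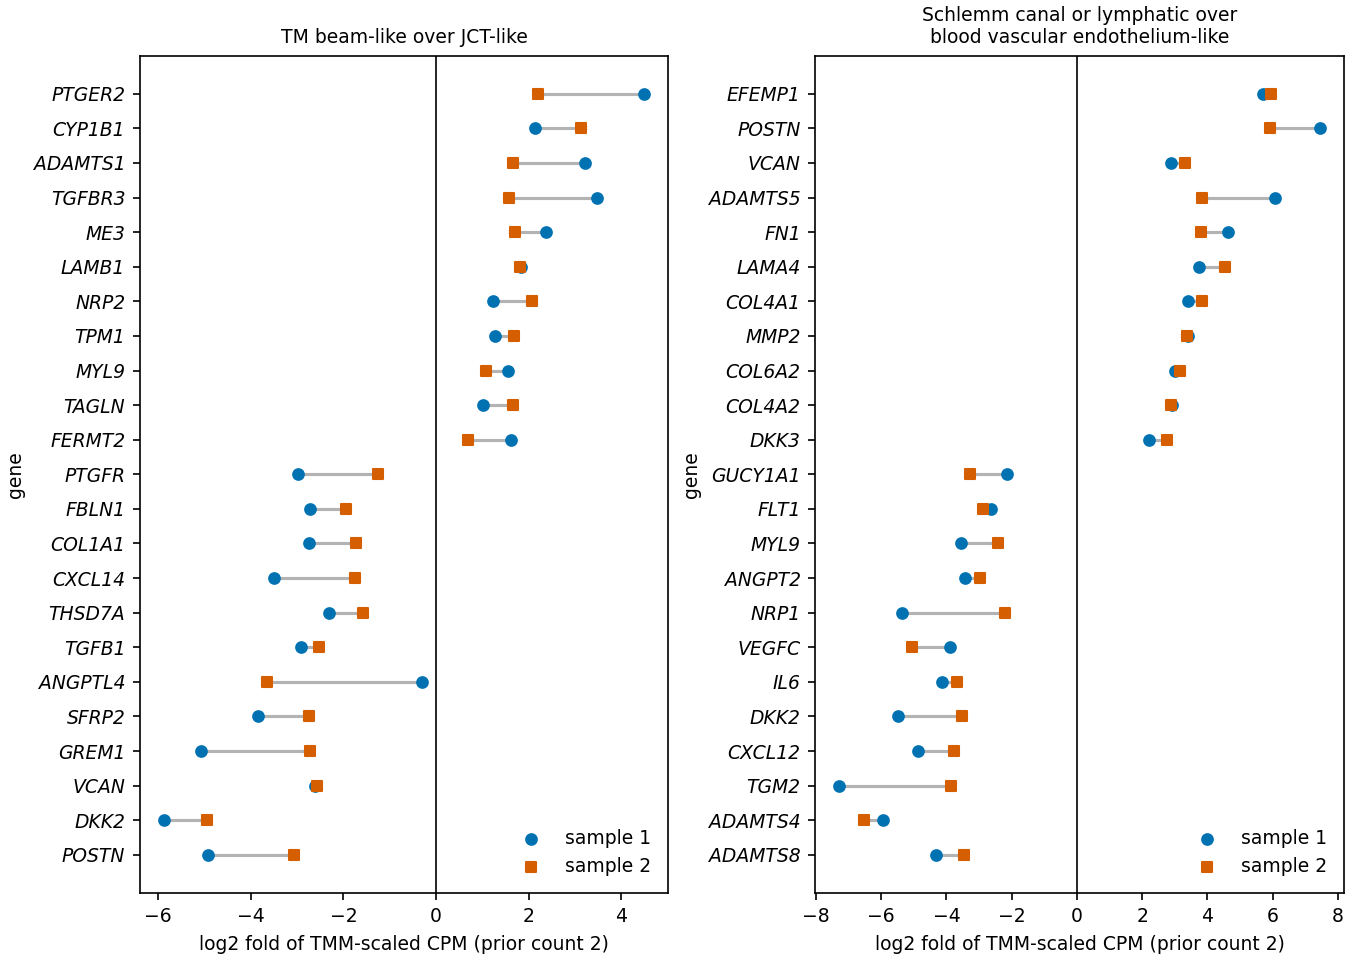
Log2 fold of TMM-scaled CPM (prior count 2) in each of the 2 samples for the named genes, beam-like over JCT-like cells on the left and Schlemm canal or lymphatic endothelium-like over blood vascular endothelium-like cells on the right. Both samples lie on the same side of 0 for each gene, though ANGPTL4 on the left is at -0.30 in sample 1 and -3.64 in sample 2; under library totals no named gene changes side.

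The second pair asked what sets the endothelium of the drainage canal, or of lymphatics, apart from that of blood vessels. In Schlemm canal-like cells COL4A1 was higher by 3.68 ± 0.25 (edgeR adjusted p = 1.57e-11), the laminin chain LAMA4 by 4.27 ± 0.30 and fibronectin FN1 by 4.33 ± 0.55. EFEMP1 had 99 counts in them and 0 in blood endothelium-like cells, at least 17.9-fold higher. Blood endothelium-like cells carried more of the crosslinking enzyme TGM2 (-5.72 ± 0.43). VEGF genes went both ways: VEGFC (-4.23 ± 0.46), the co-receptor NRP1 (-3.84 ± 0.43) and the receptor FLT1 (-2.80 ± 0.25) were lower in Schlemm canal-like cells, and the ligand PGF (1.90 ± 0.42) and the co-receptor NRP2 (1.65 ± 0.31) higher. NOS3 was lower in Schlemm canal-like cells (-2.04 ± 0.51, edgeR adjusted p = 0.0058). The nitric oxide receptor subunits GUCY1A1 (-2.78 ± 0.54) and GUCY1B1 (-1.67 ± 0.33) were lower too, and both were highest in pericyte-like cells. The blood endothelium-like cluster has RERGL and COX4I2, leading genes of the pericyte-like cluster, among its own leading genes. Whether RNA or doublets of pericyte-like cells raised the genes of this pair that are high in those cells was not tested.

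Of the 137 listed genes 28 were higher in Schlemm canal-like cells, 25 lower and 84 did not pass (32 and 28 adjusted over the list alone). Structural matrix genes were 10 higher, 2 lower and 10 not passing (12 and 2 adjusted over the list alone). They include COL6A2 (3.07 ± 0.24), COL4A2 (2.97 ± 0.26), POSTN (310 against 1 count, ratio 168, interval 29.9 to 6645) and VCAN (13 against 0 counts, at least 2.34-fold higher). Matrix turnover genes were 9 higher, 2 lower and 9 not passing, with MMP2 (3.61 ± 0.35) and ADAMTS5 (1 count in blood endothelium-like cells, ratio 59.0, interval 10.4 to 2350) higher, and ADAMTS4 lower (3 counts in Schlemm canal-like cells, ratio 75.8, interval 25.3 to 373). Angiopoietin and VEGF genes were 2 higher, 5 lower and 5 not passing, with ANGPT2 lower (3 counts, ratio 15.4, interval 4.70 to 79.7). The receptor KDR (0.38 ± 0.21) and TIE1 (0.35 ± 0.23) were not called. Contraction genes were 0 higher, 3 lower and 7 not passing, with MYL9 at -3.02 ± 0.39. Like the 2 receptor subunits, the lower genes MYL9, ADAMTS4, ANGPT2, IL6 and ADAMTS8 had a higher mean in pericyte-like than in blood endothelium-like cells.

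Early-onset genes were 2 higher (EFEMP1, COL4A1), 2 lower and 4 not passing (2 and 3 adjusted over the list alone), with FOXC1 (-1.38 ± 0.34) among the lower. Drug targets were 1 higher, 3 lower and 6 not passing (1 and 4 adjusted over the list alone). The higher one was ROCK2 (1.03 ± 0.24), a call that ended with library totals or with relative log expression factors. Open-angle loci were 2, 2 and 17 (4 and 2 adjusted over the list alone), with CAV1 higher (1.43 ± 0.25) and ADAMTS8 lower (0 counts, at least 8.01-fold). Wnt genes were 2, 2 and 5, with DKK3 higher (2 counts in blood endothelium-like cells, ratio 8.93, interval 2.28 to 76.8) and DKK2 lower (-5.10 ± 0.49). Complement and cytokine genes were 0, 2 and 7, with CXCL12 (3 counts, ratio 32.0, interval 10.4 to 160.4) and IL6 (3 counts, ratio 25.3, interval 8.06 to 128) lower. Exfoliation and angle closure loci had 1 lower gene each, with 3 and 2 not passing, and of 5 glucocorticoid response genes, 3 optic neuropathy genes and YAP1 none was called. The counts of these lists where no other is given, of matrix turnover, of angiopoietin and VEGF and of contraction did not change when adjusted over the list alone. TGM2 (-7.28 in sample 1, -3.87 in sample 2) and NRP1 (-5.35, -2.19) differed between the samples. The comparison rests on 35 Schlemm canal-like cells in sample 2 and 26 blood endothelium-like cells in sample 1.

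The third pair asked how the muscle of the ciliary body differs from the mural cells of vessels. Ciliary muscle-like cells carried CHRM3 (7.96 ± 0.56, edgeR adjusted p = 5.99e-12), the myosin light chain kinase MYLK (2.90 ± 0.33) and the muscle caveolin CAV3 (3.29 ± 0.51). Pericyte-like cells carried the angiogenic factors ANGPT2 and PGF and the proteases ADAMTS4 (-6.96 ± 0.30, edgeR adjusted p = 1.07e-15) and ADAMTS1 (-5.74 ± 0.34). PGF was at -8.84 ± 0.44, and ANGPT2 had 1 count in ciliary muscle-like and 71 in pericyte-like cells (ratio 3293, interval 572 to 131890). That ratio, like the other ratios of counts in this pair, uses library totals. In this pair they shift the median log2 fold of all genes by -1.0 against TMM scaling. Such ratios and the fitted folds are thus not on 1 scale. Caldesmon, CALD1, was lower in ciliary muscle-like cells (-4.35 ± 0.23), as was the glucocorticoid receptor NR3C1 (-4.14 ± 0.29).

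Of the 137 listed genes 20 were higher in ciliary muscle-like cells, 32 lower and 85 did not pass (22 and 33 adjusted over the list alone). Contraction genes were 5 higher, 2 lower and 3 not passing, also adjusted over the list alone, but with library totals 2 were higher and 4 lower. The calls of MYL9 (1.80 ± 0.26), TPM1 (1.45 ± 0.26) and CNN1 (1.43 ± 0.28) ended, while TAGLN stayed lower (-2.29 ± 0.40). Structural matrix genes were 1 higher, 6 lower and 15 not passing (1 and 7 adjusted over the list alone), with MFAP4 higher (3.49 ± 0.52), BGN (-5.14 ± 0.35) and FBN1 (-4.79 ± 0.66) lower, and COL14A1 at least 232-fold lower (0 and 15 counts). Matrix turnover genes were 2 higher, TGM2 (4.43 ± 0.49) and MMP2 (2.92 ± 0.53), 5 lower and 13 not passing. Angiopoietin and VEGF genes were 2 higher, 4 lower and 6 not passing (3 and 4 adjusted over the list alone). KDR was higher (0 counts in pericyte-like cells, at least 1.24-fold), as was NRP2 (2.40 ± 0.60), whose call ended with library totals. Open-angle loci were 3 higher, 6 lower and 12 not passing, with DGKG higher (2.70 ± 0.48). PDE7B, also called, had 2 counts in pericyte-like cells (ratio 2.49, interval 0.682 to 20.7) and lost its call in 7 of the alternatives.

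Early-onset genes were 2 higher, 2 lower and 4 not passing (1 and 3 with library totals). MYOC was among the higher (4.63 ± 0.80; 7.89 in sample 1, where pericyte-like cells had 2 counts, and 3.33 in sample 2). Drug targets were 1 higher, 2 lower and 7 not passing, with GUCY1A1 (-4.80 ± 0.38) and GUCY1B1 (-3.44 ± 0.26) lower. Wnt genes were 1, 0 and 8, the higher one WNT5A (0 counts in pericyte-like cells, at least 2.44-fold); with library totals 1 was higher and 1 lower. Complement and cytokine genes were 0, 3 and 6, with IL6 at -4.86 ± 0.32, and glucocorticoid response genes 1, 1 and 3 (0 and 2 with library totals). Exfoliation loci were 0, 1 and 3, and angle closure and optic neuropathy each 1, 0 and 2, calls that ended with library totals; YAP1 was not called. All counts in these lists, and in matrix turnover and the open-angle loci, were the same adjusted over the list alone. Library totals shifted the median of all genes by -1.0 here (relative log expression factors, -0.13), gave 10 higher genes, and moved the share of calls that were higher from 38.5% to 17.5%, although no called gene changed direction. Pericyte-like cells in sample 1 numbered 21.

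The fourth pair asked what distinguishes meshwork cells from stromal fibroblast-like cells. The naming parted them narrowly in places. The fibroblast-like cluster also detected 5 beam markers and had EDN3 among its leading genes. Its mean z-score was 1.63 for fibroblast and 0.519 for meshwork. In the beam-like clusters of 418 and 338 cells, meshwork scored 0.338 and 0.397 and fibroblast 0.316 and 0.348. Meshwork cells had more of the Wnt inhibitor WIF1, with 2 counts in fibroblast-like cells (ratio 148, interval 40.9 to 1224), and of SFRP1 (3 counts, ratio 49.1, interval 16.8 to 239), CXCL14 (5.51 ± 0.47) and SVEP1 (3.90 ± 0.45). GREM1 had 243 counts in them and 0 in fibroblast-like cells, at least 13.6-fold higher. Fibroblast-like cells had more SFRP4 (-4.58 ± 0.34), the proteoglycan VCAN (-5.51 ± 0.44), the protease MMP2 (-2.38 ± 0.17) and its inhibitor TIMP1 (-2.36 ± 0.20). MYOC was higher in meshwork cells (2.18 ± 0.60, edgeR adjusted p = 0.0070).

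Of the 137 listed genes 33 were higher in meshwork cells, 27 lower and 77 did not pass (34 and 29 adjusted over the list alone). Early-onset genes were 5 higher, 0 lower and 3 not passing, also adjusted over the list alone, and 2 higher with library totals: MYOC, SVEP1, ANGPT1 (1.05 ± 0.22), CYP1B1 (1.04 ± 0.31) and COL4A1 (1.04 ± 0.27). Contraction genes were 7 higher, 0 lower and 3 not passing, also adjusted over the list alone (7 higher and 1 lower with library totals), with TAGLN (2.86 ± 0.40), CNN1 (1.97 ± 0.47) and MYLK (1.86 ± 0.43). Wnt genes were 4 higher, 3 lower and 2 not passing, with FRZB (2.54 ± 0.39) also higher and DKK2 (-3.46 ± 0.23) also lower. Structural matrix genes went both ways, 7 higher, 7 lower and 8 not passing, with THBS1 (4.09 ± 0.48) and MFAP4 (2.92 ± 0.26) against COL12A1 (-2.32 ± 0.14); with library totals or relative log expression factors 6 were higher. Matrix turnover genes were 1 higher, 5 lower and 14 not passing. Angiopoietin and VEGF genes were 1 higher, 5 lower and 6 not passing, with ANGPT2 (-3.35 ± 0.63), KDR (-2.79 ± 0.33) and ANGPTL4 (-2.45 ± 0.49) lower.

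Complement and cytokine genes were 3, 3 and 3 (3 and 4 adjusted over the list alone), with CXCL14 and IL6 (3.15 ± 0.80) higher and C3 (-3.13 ± 0.40) and IL33 (-3.11 ± 0.42) lower. Open-angle loci were 3, 2 and 16 (4 and 3 adjusted over the list alone; 3 and 3 with library totals), with CAV1 (3 counts in fibroblast-like cells, ratio 13.9, interval 4.69 to 67.7) and ME3 (2.68 ± 0.70) higher. Glucocorticoid response genes were 1, 1 and 3, with the kinase SGK1 higher (1.35 ± 0.19) and TSC22D3 lower (-1.56 ± 0.15). Exfoliation loci were 1, 0 and 3, with CACNA1A (3 counts, ratio 23.5, interval 7.99 to 115) higher, and drug targets 0, 1 and 9, with CHRM3 lower (-2.16 ± 0.45); angle closure and optic neuropathy genes and YAP1 were not called. The other lists kept their counts when adjusted over the list alone. Library totals shifted the median of all genes by -0.12. IL6 (3.69 in sample 1, 0.82 in sample 2) and C3 (-5.73 and -2.48) differed between the samples, and in sample 2 alone CYP1B1 (0.86), ANGPT1 (0.76) and COL4A1 (0.63) were under the log2 minimum of 1.

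**Figure D4:**
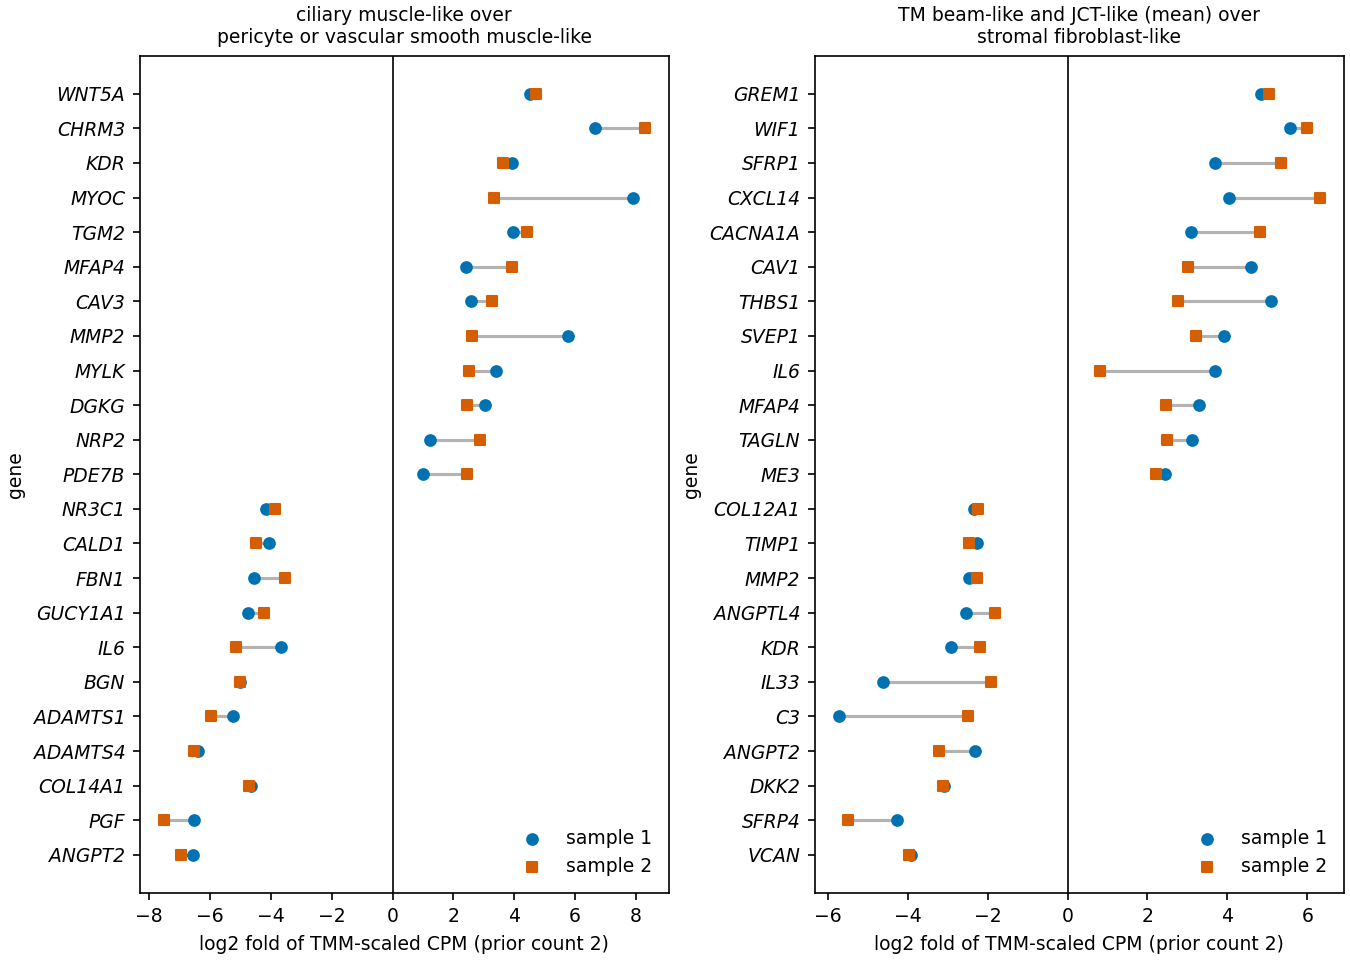
Log2 fold of TMM-scaled CPM (prior count 2) in each of the 2 samples for the named genes, ciliary muscle-like over pericyte or vascular smooth muscle-like cells on the left and meshwork (mean of beam-like and JCT-like) over stromal fibroblast-like cells on the right. Both samples lie on the same side of 0 for each named gene, which library totals did not turn, although on the left they leave 2 contraction genes higher and 4 lower in place of 5 and 2.

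Within a class the samples were compared as values only, with no test. In macrophage-like cells the haemoglobin gene HBB, a marker of red blood cells, was at 15.02 CPM (21 counts) in sample 1 and 211 CPM (626 counts) in sample 2, a ratio of 14.0 (interval 9.10 to 22.8). The rise was not particular to macrophage-like cells: in a ciliary muscle-like cluster HBB had 10 and 694 counts (ratio 41.1, 22.2 to 86.1). PTGDS, a prostaglandin synthase, had a ratio of 14.0 (6.29 to 38.6), which fell to 4.01 after thinning to 1000 UMIs; it is a leading gene of the fibroblast-like and corneal endothelium-like clusters. The calprotectin gene S100A9 had 0 and 87 counts (at least 13.7-fold), S100A8 had 0 and 54 (at least 8.48-fold) and SPARCL1 had a ratio of 8.79 (3.92 to 24.5). Higher in sample 1 were ENSMMUG00000048107 (3.59), PSMD11 (2.78), ENSMMUG00000006987 (2.35), EYA3 (2.26) and RAB8B (2.22; 4.07 after thinning). In the beam-like cluster with the most cells in sample 1, CCL2 was 2.55 times as high in sample 1 (2.01 to 3.25), followed by RPL36AL (2.28; 2.85 after thinning), RGS5 (2.13), MGA (2.12) and TMA7 (2.09). WIF1 was 3.49 times as high in sample 2 (2.92 to 4.19), followed by UNC13C (3.24), SNX21 (2.98; 6.23 after thinning), ENSMMUG00000013907 (2.90) and ISOC1 (2.67). In the largest ciliary muscle-like cluster, SPP1 (2 counts in sample 1, ratio 16.2, 4.31 to 137; 2.34 after thinning), CP (14.9), WIF1 (0 counts, at least 10.1-fold) and S100A10 (6.94; 1.67 after thinning) were higher in sample 2. All of them were at 20.6 CPM or less there, and SPP1, CP and WIF1 are leading genes of clusters of other classes. ENSMMUG00000020035 and GNG7 (1.97 each; the first 6.97 after thinning, from 7 and 3 counts), ATXN7L3B (1.95; 3.58 after thinning), MRPL2 (1.90) and FOSB (1.89) were higher in sample 1.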

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

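The tests with library totals, with a finer split, with fewer beam-like clusters and without the unnamed or mitochondrial genes were chosen only after the results had been seen; the others were planned. No named gene of the 4 pairs turned direction in a call. Against pooled cells, though, 12 calls of a class against the others did: TPM2 (-1.13) and CNN1 (-2.71) in JCT-like, CHRM3 (-4.80), MYL9 (-2.55), CAV3 (-2.22), TPM1 (-1.65) and TGM2 (-1.65) in beam-like, CHRM3 (-3.21) in fibroblast-like, DGKG (-2.18) in Schwann-like and MYLK (-1.06) in pericyte-like cells, and CCL2 in Schlemm canal-like (-1.60) and blood endothelium-like cells (-1.69). The balance of higher and lower genes turned to mostly lower in ciliary muscle-like cells with library totals, DESeq2 and pooled cells, and against pooled cells in Schwann-like cells and both endothelia. In the pair of endothelia (28 and 25) it was 25 and 26 with relative log expression factors. Of the counts, 358 of 390 for a class against the others and 127 of 128 for the pairs stayed within 1.5 times the reported count. Of the shares, 164 of 192 stayed within their counting interval. These include all 24 at the minimum of 200 genes, which kept the same cells and so could change no share. Among 1531 folds of named genes, 1417 kept their side of the threshold or, with 1 replicate left out, moved by less than 1 SD. Another 32 lost their call, and 82 moved by more when 1 replicate was left out. That SD is taken from the same 2 folds, which lie within 1 SD of their mean by construction. The folds with 1 replicate left out therefore say little about how far the samples agree. Without the replicate block (no pairing of classes by sample) every count stayed within 1.5 times, and the calls of MYL9, TAGLN, FERMT2 and PDE7B ended. Of the 32 lost calls, 14 came with DESeq2. Relative log expression factors, resolution 0.5 and fits without the unnamed genes changed no count or share beyond these bounds. For the values below the cause was not tested unless given.

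Without the low-count filter, which tests more genes, lower genes numbered 3 in JCT-like, 25 in melanocyte-like and 6 in pericyte-like cells. With DESeq2 they numbered 51 in ciliary muscle-like, 80 in macrophage-like, 5 in pericyte-like, 11 in fibroblast-like and 12 in beam-like cells. Against pooled cells, where large classes weigh more by construction, higher and lower genes were 24 and 74 in ciliary muscle-like, 35 and 17 in JCT-like, 18 and 52 in Schwann-like, 42 and 39 in fibroblast-like and 44 and 31 in beam-like cells, and lower genes were 44 in blood endothelium-like, 100 in macrophage-like, 55 in melanocyte-like, 26 in pericyte-like, 52 in Schlemm canal-like and 93 in T or NK-like cells. With library totals, ciliary muscle-like cells, whose TMM factor is the lowest, had 26 higher and 37 lower, JCT-like cells 2 lower, and ciliary muscle against pericyte 10 higher. The 1 lower gene of JCT-like cells became 0 with the listed genes in the clustering, 0 at resolution 2 and 2 with doublets kept. Leaving out a replicate gave 0 to 1 lower genes in JCT-like and 9 to 13 in Schlemm canal-like cells, counted without a test as the called genes whose fold in the remaining sample was still at least 1 in size.

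JCT-like cells were 1.14% of sample 1 with a finer split, and in sample 2 they were 0.963% at resolution 2, 0.963% with the listed genes, 0.878% scaled together, 0.573% among cells with 1000 genes and 0.595% with a finer split. The counterpart, corneal endothelium-like cells, were 2.34% of sample 1 with the finer split, and in sample 2 they were 0.878% at resolution 2, 0.906% with the listed genes, 0.878% scaled together, 1.07% with 1000 genes and 1.25% with the finer split. Cells with 1000 genes or more, by construction fewer of the shallow classes, gave 2.40% and 1.86% Schwann-like, 1.16% and 0.823% T or NK-like and 23.3% and 28.5% ciliary muscle-like cells in samples 1 and 2, 23.1% beam-like in sample 1, and 2.01% pericyte-like and 7.56% fibroblast-like in sample 2; 12.1% and 5.91% were then unnamed. Ciliary muscle-like cells of sample 2 were 27.1% at resolution 2 and 27.1% with the listed genes, and macrophage-like cells 17.95% at resolution 2. Pericyte-like cells were 0.695% of sample 1 in both of these, and 0.963% and 1.02% of sample 2, which left 11 cells in sample 1, so that ciliary muscle against pericyte was not run there. With the finer split no JCT-like test was run.

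Of the 25 ratios between the samples that have a value after thinning to 1000 UMIs, 17 stayed within their counting interval and 8 left it, with log2 ratios of 1.51 for RPL36AL, -2.64 for SNX21, 2.80 for ENSMMUG00000020035, 1.84 for ATXN7L3B, -1.23 for SPP1, -0.74 for S100A10, 2.02 for RAB8B and -2.00 for PTGDS. These were limited to the 3 units reported here after all had been seen. The interval covers the error of the full counts only. Some thinned counts are small, such as 1 and 9 for SNX21 and 6 and 5 for ATXN7L3B in samples 1 and 2. A ratio that left its interval thus need not show an effect of depth. Depth limits the genes with 3 counts or fewer in a class and the classes near 20 cells in a sample.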

Other observations

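The tests on the Schlemm canal share were chosen only after the shares had been seen; those on the interferon-led cells and on the 2 libraries were planned before their results. The dissociation stress genes (7 of 10 in the table, among them FOS, JUNB and EGR1) took the largest share of UMIs in Schwann-like cells, 1.42% in sample 1 and 1.25% in sample 2, followed by fibroblast-like cells (1.03% and 1.01%), pericyte-like cells (0.927% and 0.955%), blood endothelium-like cells (0.810% and 0.930%) and melanocyte-like cells (0.758% and 0.716%). Beam-like cells had 0.687% and 0.657%, JCT-like cells 0.571% and 0.372%, Schlemm canal-like cells 0.410% and 0.591% and ciliary muscle-like cells 0.257% and 0.277%. Macrophage-like cells had 0.120% and 0.159% and T or NK-like cells 0.0379% and 0.0303%.

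One beam-like cluster of 57 cells was led by the interferon-induced genes IFIT1, ISG15, IFI27, MX1 and IFIT3, and 56 of its cells came from sample 2. These 5 genes summed to 7072 CPM in it, against 364 CPM in the other beam-like cells of that sample. They were taken from its own leading genes, so a gap follows from the choice. In blood endothelium-like cells, which IFI27 also leads, they summed to 2282 CPM in sample 1 and 3149 CPM in sample 2. Doublets with macrophages, or their RNA, are argued against by 5 macrophage markers (CD163, C1QB, CD74, MRC1, AIF1), whose median was 0.0% of the level in macrophage-like cells. A rise over the whole library is argued against as the whole cause by a median ratio of sample 2 to sample 1 of 1.30 over the 11 classes without these cells, although 5 of the 11 had intervals above 1: Schlemm canal-like (3.19, interval 2.06 to 4.94), macrophage-like (3.05, 2.58 to 3.63), Schwann-like (1.60, 1.23 to 2.11), blood endothelium-like (1.38, 1.22 to 1.57) and the other beam-like cells (1.31, 1.21 to 1.43). The source of the interferon genes stays open. The design names no biological difference between the samples, so none was tested.

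The share of Schlemm canal-like cells was 5.94% in sample 1 and 0.991% in sample 2. Deeper cells in sample 1 are argued against, since among cells with at least 1000 genes the shares kept a ratio of 7.55 (7.03% and 0.931%). More tissue taken at the canal in sample 1 is a candidate explanation, since the JCT-like share, the layer next to the canal, was 2.47 times as high in sample 1. That test was written after the shares were seen, and JCT-like shares move with the split of the mixed cluster. No biological explanation was tested, since the samples form 1 group.

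Whether the libraries come from 1 animal was tested by genes near 0 in all classes of one library and high in the other, as a variant carried by 1 of 2 animals could give. If both libraries come from 1 animal the count should be 0, and it was 0. The 2 libraries of different animals without such variants could also give 0, so neither is excluded.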
